A study of Homo sapiens with 6 samples.

How the data were processed

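Total RNA of SKOV3ip1, a taxane-sensitive human ovarian carcinoma cell line, and SKOV3TRip2, a taxane-resistant line of the same SKOV3 background, was hybridised to Illumina BeadChip expression arrays. Per the labels, cells of both lines were grown without treatment on routine culture plates, and each line was collected 3 times. Per the labels' protocols, RNA was purified on RNeasy columns and amplified to biotinylated cRNA. The 6 arrays lay on 3 chips with 1 array of each line per chip, per the labels. Chip 1 held SKOV3ip1 collection 1 and SKOV3TRip2 collection 3, chip 2 held SKOV3ip1 collection 2 and SKOV3TRip2 collection 1, and chip 3 held SKOV3ip1 collection 3 and SKOV3TRip2 collection 2. The labels do not say whether the collections came from separate thaws or passages, so p-values measure the spread between these collections.

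The deposited table gave the average bead signal intensity of 22184 probes on each array, on a linear scale. BeadStudio 3.1 is named in the submitters' processing notes. The normalization method and the treatment of background are not given in the sources used here. The values show that arrays had been brought to a common scale before deposit, since the quartiles of the 6 arrays differed by at most 0.127%. Deposited intensity values ran from 41.94 to 37995 and none was negative. Detection p-values were not used here. A scaling of this kind fixes the median of each array, so a shift common to most genes could not be seen.

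Intensity values were taken as deposited and converted to log2. A floor of 16 was planned and touched no value. Gene symbols came from the platform annotation, which gave 19715 probes 1 symbol, 0 probes several and 2469 probes none. The Entrez identifiers of 19695 probes were found among the RefSeq genes of assembly GRCh38.p14, and 0 symbols needed an update. That table served only for names, gene order and gene length. The genome build behind the probes is not given in the sources used here, so no coordinate is printed.

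With no detection p-value, background was set on each array at the 95th percentile of 447 probes for olfactory receptors, taste receptors and keratin-associated proteins. It lay between 103.4 and 107.7 intensity units on the SKOV3ip1 arrays and between 96.4 and 97.4 on the SKOV3TRip2 arrays. Probes above it on at least 3 of the 6 arrays, whatever the line, were tested. That left 12998 probes, of which 11876 were named, for 10696 genes, and 9186 probes were not tested. Where a gene had several tested probes, as 993 genes did, the probe with the highest mean over the 6 arrays stood for it. Where a probe was not above background on any array of a line, the fold is a lower bound, written as at least N-fold. It sets the mean log2 value of the brighter line against the mean, per array of the dimmer line, of the higher of its background bound and the probe's own value.

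Lines were compared as SKOV3TRip2 minus SKOV3ip1 with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend on log2 values, without covariates. Adjusted p-values are limma's two-sided p-values after Benjamini-Hochberg adjustment over the 12998 probes, with a threshold of 0.05. The 32 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 and with fry. This held for 29 lists, over which the p-values of camera and of fry were each adjusted by Benjamini-Hochberg. The lists covered ABC drug transporters, the chromosomal neighbours of ABCB1, tubulins and microtubule regulators, the mitotic spindle and checkpoint, DNA replication, aldehyde dehydrogenases, genes associated with stem cells, the Notch, Hedgehog and Wnt pathways, BCL2 and IAP apoptosis regulators, epithelial adhesion and keratins, mesenchymal genes, collagens, matrix and integrins, interferon-stimulated genes, NF-kB and inflammatory mediators, antigen presentation, NRF2 targets, cytochromes P450 and nuclear receptors, growth factor receptors and ligands, the unfolded protein and integrated stress response, heat shock proteins, hypoxia and glycolysis, cholesterol synthesis, p53 targets, histones, cancer-testis antigens, immediate early genes, and markers of leukocytes, endothelium, fibroblasts and mesothelium.

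The naming rule takes the 12 largest increases and the 12 largest decreases among called genes whose lines did not overlap, the genes of interest ABCB1, ALDH1A1, JAG1, SMO, GLI1, PTCH1, TUBB3, EDNRA and ERBB2, and the 2 highest and 2 lowest members of each list. Genes named outside it are said to be chosen after their values were seen. EDNRA was not analysed here, since no probe carried that symbol.

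The fit was tested on simulated data built from the real probe means, with the real spreads shuffled among probes. Noise was drawn independently for each probe, and 50 of the 12998 probes were changed at each of 4 sizes. It called 8% of the probes changed 1.5-fold, 50% of those changed 2-fold, 96% of those changed 4-fold and 98% of those changed 8-fold. Of 132 calls, 6 were false, or 4.55%. Far fewer probes were changed here than passed in the real data, and real arrays shared deviations across probes. These rates therefore need not hold for the real calls. Only 3 arrays per line limit the precision, and small differences can be missed. Alternatives were median scaling, quantile normalization, other floors and filters, blocks for the collection number and for the chip, array weights, an eBayes fit without trend, other list settings and leaving out each array. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.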

Results

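Gene expression was measured in the taxane-sensitive ovarian carcinoma line SKOV3ip1 and in the taxane-resistant line SKOV3TRip2, with 3 collections of untreated cells of each line. Taxanes are drugs that stabilise microtubules. Between 54.6% and 58.7% of the 22184 probes lay above background on each array. Collections of the same line correlated across probes at r = 0.969 to 0.994, and arrays of different lines at r = 0.872 to 0.931. These are correlations across probes, which are not independent replicates. SKOV3ip1 collections 2 and 3 stood closest, with 9 probes over 2-fold apart, against 227 to 378 for the other pairs within a line.

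The comparison asked which genes differ between 1 taxane-sensitive and 1 taxane-resistant line. With 1 line of each kind, resistance cannot be told apart from any other difference between the lines. The resistant line had high ABCB1, which encodes the efflux pump P-glycoprotein that exports taxanes, and high ALDH1A1, an aldehyde dehydrogenase of retinoic acid synthesis. It also had high CLDN16, a tight junction protein, and the chemokine CCL2, and low SPANX family transcripts, the matrix protein TGFBI and the calcium-binding protein S100A4. ABCB1 stood at a mean intensity of 7212 in SKOV3TRip2 (log2 12.82 ± 0.38, SD, n = 3) and was not above background on any SKOV3ip1 array, at 66.8 (log2 6.06 ± 0.03, SD, n = 3). In limma, 3694 of 12998 probes (28.4%) passed an adjusted p of 0.05. Of these, 1903 were higher and 1791 lower in SKOV3TRip2, representing 1632 and 1553 genes. At least a 2-fold change was seen for 1204 of them, 616 higher and 588 lower. At 5652 tested probes, or 43.5%, the arrays of the lines did not overlap, against the 10% that chance gives. With the chip as a block, 3351 probes passed. The line difference within chip 1, 2 or 3 correlated with the mean difference on the other chips at r = 0.722, 0.881 and 0.835, across probes. The count depended on single arrays: it was 2146 without SKOV3ip1 collection 2, 1864 without SKOV3ip1 collection 3 and 2245 without SKOV3TRip2 collection 2. It also depended on how the collections were weighted: array weights, highest for SKOV3ip1 collection 3, gave 6222. SKOV3ip1 collections 2 and 3 were close enough that their independence is uncertain, and averaging them as 1 sample, an alternative chosen after seeing the data, gave 2069.

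**Figure D1:**
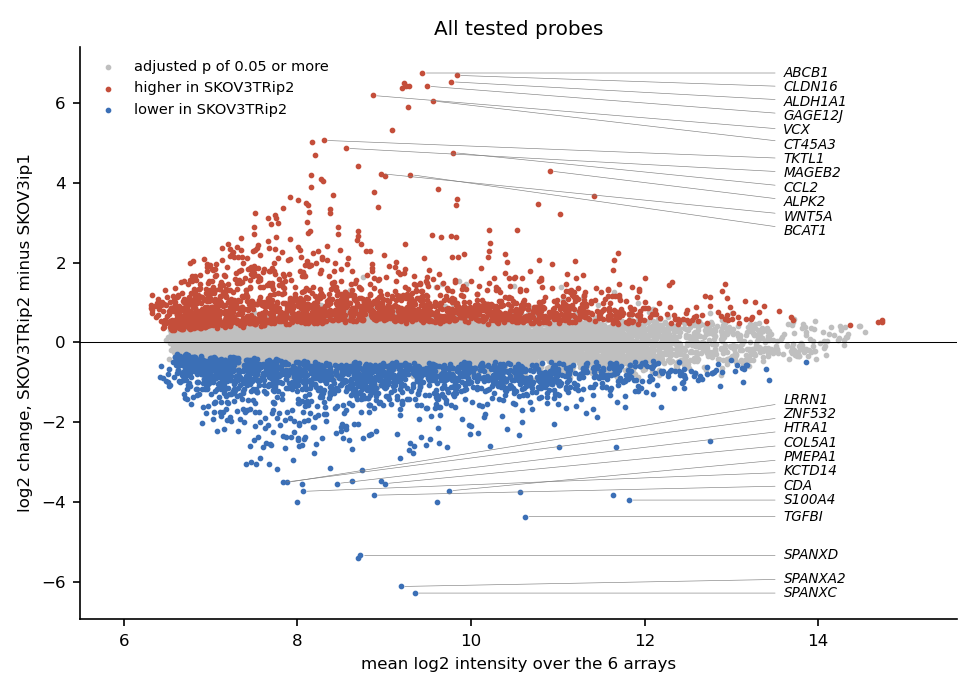
Log2 change of each tested probe, SKOV3TRip2 minus SKOV3ip1, against its mean log2 intensity over the 6 arrays, with the 24 genes of largest change named. Red and blue points are the 1903 higher and 1791 lower probes at a limma adjusted p under 0.05, and the change runs from -6.29 to 6.75.

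Among the largest increases, ABCB1 rose by 6.75 on the log2 scale (95% confidence interval 6.29 to 7.22, limma adjusted p = 6.47e-08), at least 68.8-fold. CLDN16 rose at least 88.7-fold (log2 6.70, SE 0.223, limma adjusted p = 7.47e-08) and ALDH1A1 at least 80.3-fold (log2 6.53, SE 0.167, limma adjusted p = 3.12e-08). The germline genes GAGE12J, VCX, CT45A3 and MAGEB2 rose at least 63.7-, 38.1-, 58.6- and 19.4-fold. Dimmer CT45A3 probes rose by log2 5.32, 4.42 and 1.34. GAGE, VCX and CT45 members are near-identical copies, so the member measured is uncertain. TKTL1, a transketolase-like protein, rose at least 17.4-fold. CCL2 rose 27.1-fold, from an intensity of 170 to 4611 (limma adjusted p = 1.11e-06). The alpha kinase ALPK2, the secreted ligand WNT5A and the branched-chain aminotransferase BCAT1 rose by log2 4.30, 4.23 and 4.21. WNT5A lay near background in SKOV3ip1, at a mean intensity of 115, so the size of its rise is not exact. By the naming rule, all 12 genes were higher on every SKOV3TRip2 array than on any SKOV3ip1 array.

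Among the largest decreases, SPANXC fell from an intensity of 5778 to 73.9, at least 59.6-fold (log2 -6.29, SE 0.214, limma adjusted p = 7.47e-08). SPANXA2 and SPANXD, near-identical relatives whose signals cannot be assigned to a member, fell at least 50.3- and 27.8-fold. TGFBI changed by log2 -4.37 (SE 0.320, limma adjusted p = 9.69e-06) and S100A4 by log2 -3.96 (SE 0.320, limma adjusted p = 1.92e-05), with S100A4 at an intensity of 14260 in SKOV3ip1 and 918 in SKOV3TRip2. CDA, the deaminase that inactivates cytidine analogues, changed by log2 -3.84. KCTD14, ZNF532 and LRRN1 fell at least 10.1-, 7.93- and 8.23-fold. PMEPA1, a transmembrane protein induced by TGF-beta, changed by log2 -3.73, the collagen chain COL5A1 by -3.55 and the secreted protease HTRA1 by -3.54. HTRA1 and CDA lay near background in SKOV3TRip2, at mean intensities of 103 and 125, so the size of their falls is not exact. On every SKOV3TRip2 array these 12 genes lay below all SKOV3ip1 arrays, as the naming rule requires.

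Of the genes of interest, JAG1, a Notch ligand, was higher in SKOV3TRip2, besides ABCB1 and ALDH1A1. Its mean intensity was 238 in SKOV3ip1 and 702 in SKOV3TRip2, a 2.95-fold rise (log2 1.56, 95% confidence interval 1.14 to 1.98, limma adjusted p = 0.000267). Within chips 1, 2 and 3 the difference was 1.33, 1.34 and 2.01 for JAG1, 6.36, 6.96 and 6.95 for ABCB1 and 6.31, 6.59 and 6.70 for ALDH1A1. For ABCB1 and ALDH1A1 the SKOV3ip1 values lay in the background, so the size of their differences is not exact. SMO, the Hedgehog signal transducer, differed by log2 0.29 (95% confidence interval -0.08 to 0.67, limma adjusted p = 0.213). TUBB3, the class III beta-tubulin, differed by log2 -0.48 (95% confidence interval -1.05 to 0.09, limma adjusted p = 0.183), and without SKOV3ip1 collection 1 it passed, at log2 -0.72 with a limma adjusted p of 0.0382. ERBB2 differed by log2 0.18 (95% confidence interval -0.35 to 0.71, limma adjusted p = 0.600), and a dimmer ERBB2 probe by log2 -0.33 (limma adjusted p = 0.106). The brighter ERBB2 probe changed sign between chips, at -0.301, 0.625 and 0.216 within chips 1, 2 and 3. GLI1 and PTCH1, both Hedgehog targets, were not above background on any array. Thus 3 of the 6 tested genes of interest passed.

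**Figure D2:**
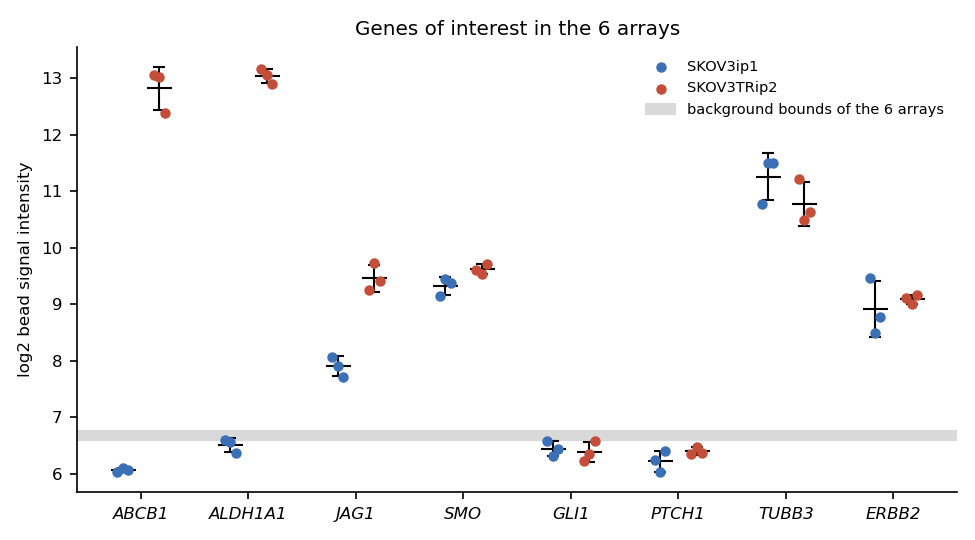
Log2 bead signal intensity of the genes of interest on each of the 6 arrays, as points, with the mean and SD of 3 collections per line as bars, and the range of background bounds shaded. ABCB1 and ALDH1A1 lie below background in SKOV3ip1 and at mean intensities of 7212 and 8423 in SKOV3TRip2, and GLI1 and PTCH1 lie below background in both lines.

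Among ABC drug transporters, ABCB1 and the conjugate exporter ABCC2 (log2 1.76) rose, and ABCC4 (log2 -1.41) and ABCC3 (log2 -2.67) fell. Of 10 tested members, 3 rose, 3 fell and 4 did not pass, and 6 passed adjusted over the list alone. As a group they did not stand apart from other genes (limma camera adjusted p = 0.898), and their median of -0.10, mean of 0.39 and the upward test differed in sign.

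Several genes beside ABCB1 on its chromosome were higher as well. The semaphorin SEMA3A rose by log2 1.87 (limma adjusted p = 0.000841). Of 20 tested neighbours, ABCB1 included, 9 rose, 0 fell and 11 did not pass, and 10 passed adjusted over the list alone. The lowest members were FZD1 at -0.20 and SRI at -0.18, and a second SRI probe fell (log2 -0.57, limma adjusted p = 0.0297). ELAPOR2 (log2 1.78), CROT (log2 0.93) and CLDN12 (log2 0.90), chosen after their values were seen, rose too. Across the list the median was 0.57 (limma camera adjusted p = 0.000565, adjusted p = 0.781 with an estimated correlation, and fry adjusted p = 0.00865), and 0.38 without SKOV3TRip2 collection 2. With ABCB1 itself left out, a test added after seeing the data, the median of the other 19 genes was 0.53 (limma camera adjusted p = 0.00278, and adjusted p = 0.781 with an estimated correlation). Within chips 1, 2 and 3 the median with ABCB1 was 0.19, 0.59 and 0.81. Of the 24 tested genes nearest to ABCB1, 13 rose and 0 fell. With the chip as a block 11 of these calls were kept, and CD36 (limma adjusted p = 0.059) and RUNDC3B (limma adjusted p = 0.0668) were lost. Only 9 were kept without SKOV3ip1 collection 2, 8 without SKOV3ip1 collection 3, 10 without SKOV3TRip2 collection 1 and 8 without SKOV3TRip2 collection 2, and the losses were among CD36, RUNDC3B, RSBN1L, DMTF1 and SLC25A40, named here after their values were seen.

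**Figure D3:**
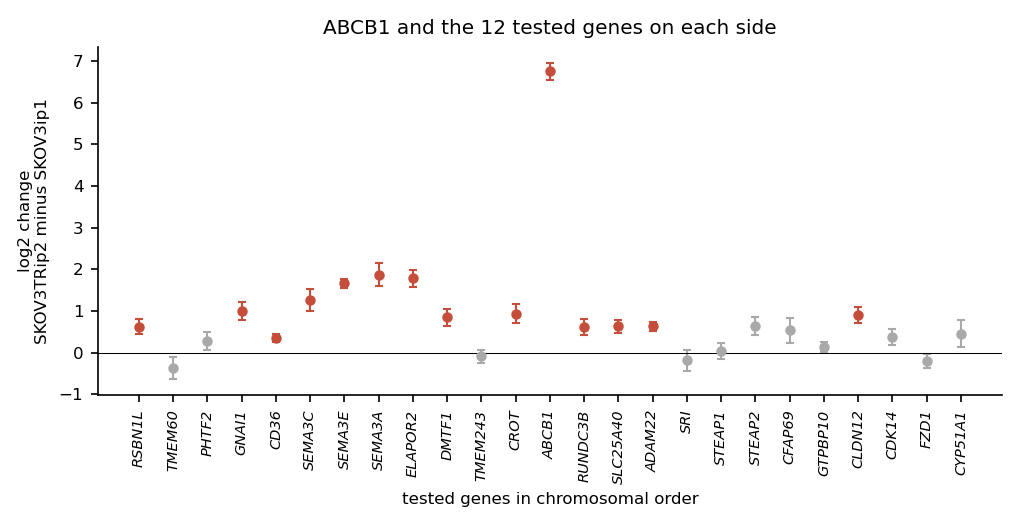
Log2 change, SKOV3TRip2 minus SKOV3ip1, of ABCB1 and the 12 tested genes on each side of it, in chromosomal order. Points are limma estimates with SE bars, red at an adjusted p under 0.05, and 13 of the 24 neighbours passed, all upward, or 11 with the chip as a block, with SEMA3A highest at 1.87.

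Tubulin genes moved apart. The beta-tubulin TUBB2B rose by log2 3.84 (SE 0.221, limma adjusted p = 2.12e-06) and the kinesin adaptor FEZ1 by log2 1.82, whereas the alpha-tubulin TUBA4A changed by log2 -3.48 (SE 0.266, limma adjusted p = 1.28e-05) and DPYSL2, a tubulin-binding protein, by log2 -1.61. Dimmer FEZ1 probes rose by log2 1.04 and 0.54. Of 42 tested tubulins and microtubule regulators, 7 rose, 9 fell and 26 did not pass, with 17 passing adjusted over the list alone. The list did not stand apart (limma camera adjusted p = 0.541).

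Some cell cycle genes were lower in the resistant line, and most did not pass. In the mitotic spindle and checkpoint list 0 of 43 members rose, 6 fell and 37 did not pass, and 5 passed adjusted over the list alone. The centromere proteins CENPM and CENPA fell, by log2 -1.30 and -0.94, and the highest members, PLK4 and NDC80, stood at 0.21 and 0.17. Of 33 DNA replication genes, 1 rose, 9 fell and 23 did not pass, and 11 passed adjusted over the list alone. Cyclin CCNE2 (log2 -1.48) and thymidine kinase TK1 (log2 -1.31) fell, the licensing factor CDT1 rose by log2 0.73, and MCM3 stood at 0.28. The TK1 call was lost without SKOV3ip1 collection 3 (limma adjusted p = 0.0595), and the CDT1 call without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 1 (limma adjusted p = 0.0853, 0.139 and 0.0816). Without SKOV3TRip2 collection 1 the change of CDT1 was log2 0.47. Limma camera gave adjusted p = 0.0208 for the mitotic and 0.00282 for the replication list, and adjusted p = 0.822 for each with an estimated correlation. By fry neither list passed (adjusted p = 0.344 and 0.272), and in both the mean of SKOV3TRip2 collection 1 (0.21 and 0.19) lay above that of SKOV3ip1 collection 1 (0.06 and 0.03). The median of the mitotic list was -0.24, or -0.16 without SKOV3ip1 collection 2, -0.39 without SKOV3TRip2 collection 1 and -0.14 without SKOV3TRip2 collection 2. That of the replication list was -0.46, or -0.73 without SKOV3TRip2 collection 1. The mitotic median was -0.29, 0.05 and -0.55 within chips 1, 2 and 3, and the replication median -0.42, -0.21 and -0.87. The mitotic call was lost without SKOV3ip1 collection 2 (adjusted p = 0.0544), SKOV3TRip2 collection 2 (adjusted p = 0.161) or SKOV3TRip2 collection 3 (adjusted p = 0.122).

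Outside ALDH1A1, most aldehyde dehydrogenases that passed were lower. ALDH1L1 rose (log2 0.81, at least 1.02-fold), and ALDH3A1 (log2 -1.50, at least 2.41-fold) and the retinaldehyde dehydrogenase ALDH1A3 (log2 -1.36) fell. Of 14 tested members, 2 rose, 5 fell and 7 did not pass, and 7 passed adjusted over the list alone (limma camera adjusted p = 0.813). The median of -0.01 and camera pointed down, and the mean of 0.17 and fry pointed up. Among genes associated with stem cells, the adhesion protein EPCAM (log2 -2.61) and the receptor KIT (log2 -2.22, at least 3.54-fold) fell, MYC rose by log2 0.83 and BMI1 stood at 0.43. Of 12 members, 1 rose, 6 fell and 5 did not pass, with 7 passing adjusted over the list alone (limma camera adjusted p = 0.0542). The MYC call was lost without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 2 or 3 (limma adjusted p = 0.0912, 0.0873, 0.0578 and 0.0529). Without SKOV3TRip2 collection 2 its change was log2 0.53. The BMI1 call was gained without SKOV3ip1 collection 1 (limma adjusted p = 0.0372). The list passed without SKOV3ip1 collection 1, 2 or 3 (adjusted p = 0.0359, 0.0379 and 0.0314) and with the chip as a block (adjusted p = 0.0323), but not with an estimated correlation (adjusted p = 0.781).

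Signalling pathways held members that changed in both directions, and camera called none of these lists. Camera asks only for a shift in 1 direction, so it does not show that few members changed. In the Notch list the effector HEYL (log2 1.98) and the ligand DLL1 (log2 1.79, at least 2.20-fold) rose with JAG1, HES6 fell (log2 -0.90), and the glycosyltransferase LFNG stood at -0.89. Of 30 members, 6 rose, 2 fell and 22 did not pass, and 8 passed adjusted over the list alone (limma camera adjusted p = 0.415). The LFNG value passed without SKOV3ip1 collection 1 (log2 -1.39, limma adjusted p = 0.00687). In the Hedgehog list STK36 (log2 0.84) and CSNK1A1 (log2 0.66) rose, and the transcription factor GLI2 (log2 -0.77) and the co-receptor BOC (log2 -0.56) fell, with 4 members up, 3 down and 6 not passing among 13, and 7 passing adjusted over the list alone (limma camera adjusted p = 0.813). Its median of -0.01 and mean of 0.08 differed in sign. The STK36 call was lost without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 1 or 2 (limma adjusted p = 0.0735, 0.104, 0.0639 and 0.0535), and that of CSNK1A1 without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 2 or 3 (limma adjusted p = 0.101, 0.155, 0.117 and 0.0802) and with the chip as a block (limma adjusted p = 0.0526). A dimmer CSNK1A1 probe rose by log2 1.17 (limma adjusted p = 0.00374).

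In the Wnt list WNT5A and the inhibitor NKD2 (log2 2.05) rose, and the ligands WNT7A (log2 -1.66) and WNT3A (log2 -1.56) fell. Of 29 members, 5 rose, 9 fell and 15 did not pass, with 15 passing adjusted over the list alone (limma camera adjusted p = 0.415). Among growth factor receptors and ligands, IGFBP5 (log2 2.29) and the receptor ERBB4 (log2 1.53, at least 1.68-fold) rose, and IGFBP7 (log2 -2.64) and IGFBP1 (log2 -1.92, at least 2.61-fold) fell. Of 44 members, 9 rose, 14 fell and 21 did not pass, with 26 passing adjusted over the list alone (limma camera adjusted p = 0.415).

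Apoptosis regulators differed in both directions. The TRAIL receptor TNFRSF10B rose (log2 1.37), and the pro-apoptotic BAX (log2 -0.84) and BIK (log2 -0.80) fell. CASP8, the initiator caspase, gave opposite calls from 2 probes, at log2 1.19 and -0.57. Of 30 BCL2 and IAP apoptosis regulators, 6 rose, 4 fell and 20 did not pass, with 11 passing adjusted over the list alone (limma camera adjusted p = 0.697). The BAX call was lost without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 2 or 3 (limma adjusted p = 0.0567, 0.068, 0.0709 and 0.0616). The BIK call was lost without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 1 or 2 (limma adjusted p = 0.0759, 0.175, 0.103 and 0.152) and with the chip as a block (limma adjusted p = 0.0503). Within chip 1 BIK did not fall, at a difference of 0.00141.

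Many mesenchymal genes were lower in the resistant line, led by TGFBI and S100A4. Of 22 mesenchymal genes and EMT regulators, 3 rose, 9 fell and 10 did not pass, and 15 passed adjusted over the list alone. The cadherin CDH11 rose (log2 1.56, at least 1.78-fold), as did TGFB2 (log2 1.03). The actin-binding TPM2 (log2 -2.62), the transcription factor SNAI2 (log2 -2.05) and N-cadherin CDH2 (log2 -1.99), chosen after their values were seen, fell. The list's median was -0.36 (limma camera adjusted p = 0.027, adjusted p = 0.781 with an estimated correlation, and fry adjusted p = 0.00976), and -0.31, -0.24 and -0.60 within chips 1, 2 and 3. Its call was lost without SKOV3TRip2 collection 3 (adjusted p = 0.0735).

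Epithelial genes moved both ways. Keratin KRT5 (log2 1.61) and the claudin CLDN3 (log2 1.49) rose, and EPCAM (log2 -2.61) and CLDN7 (log2 -1.62, at least 2.18-fold) fell. Of 28 members, 8 rose, 7 fell and 13 did not pass, with 15 passing adjusted over the list alone (limma camera adjusted p = 0.868), and the median of 0.01 and mean of -0.01 differed in sign. Among collagens, matrix and integrins, the basement membrane collagen COL4A5 (log2 3.40) and the integrin ITGB8 (log2 2.15) rose, and COL5A1 and COL7A1 (log2 -2.38) fell. Of 34 members, 8 rose, 8 fell and 18 did not pass, with 17 passing adjusted over the list alone (limma camera adjusted p = 0.720).

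Many interferon-stimulated genes were higher in the resistant line. The antiviral MX1 rose by log2 2.65 (limma adjusted p = 0.000124) and OAS2 by log2 2.29, at least 3.80-fold, whereas the tetherin BST2 (log2 -2.27) and IFITM1 (log2 -1.08) fell. A dimmer OAS2 probe rose by log2 0.86. Of 37 members, 20 rose, 3 fell and 14 did not pass, and 24 passed adjusted over the list alone. The median of the list was 0.56 (limma camera adjusted p = 0.000322, adjusted p = 0.781 with an estimated correlation, and fry adjusted p = 0.0397), and 0.41, 0.61 and 0.67 within chips 1, 2 and 3.

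Some NF-kB targets and inflammatory mediators were higher too. The chemokines CCL2 and CCL20 rose, CCL20 by log2 3.67 (limma adjusted p = 5.35e-06), as did CXCL2 (log2 2.08) and the cyclooxygenase PTGS2 (log2 2.07, at least 2.74-fold), the latter pair chosen after their values were seen. IL1B fell (log2 -0.71), and PTGES stood at -0.62. Of 32 members, 14 rose, 2 fell and 16 did not pass, and 18 passed adjusted over the list alone. Across the list the median was 0.59 (limma camera adjusted p = 0.0024, adjusted p = 0.813 with an estimated correlation, and fry adjusted p = 0.054), and 0.42, 0.52 and 0.92 within chips 1, 2 and 3. The IL1B call was lost without SKOV3ip1 collection 1 or 3 or SKOV3TRip2 collection 1 or 3 (limma adjusted p = 0.0719, 0.0919, 0.107 and 0.105). PTGES passed without SKOV3ip1 collection 1 (log2 -0.996, limma adjusted p = 0.00763).

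Some antigen presentation genes were higher. The class II chain HLA-DPA1 rose by log2 2.62, at least 3.84-fold (limma adjusted p = 5.58e-06), and the invariant chain CD74 by log2 1.31, while HLA-F (log2 0.06) and PSMB10 (log2 -0.08) were the lowest members. Of 18 members, 8 rose, 0 fell and 10 did not pass, and 8 passed adjusted over the list alone. The list's median was 0.50, or 0.46 with members at their bound (limma camera adjusted p = 0.00113, adjusted p = 0.781 with an estimated correlation, and fry adjusted p = 0.0531), and 0.43, 0.53 and 0.55 within chips 1, 2 and 3.

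A few stress response genes were higher in the resistant line, and the list varied widely between collections. The serine synthesis enzyme PHGDH (log2 2.23, limma adjusted p = 0.0251) and asparagine synthetase ASNS (log2 2.07, limma adjusted p = 0.0472) rose, SDF2L1 fell (log2 -1.20), and MANF stood at -0.73. Of 35 members of the unfolded protein and integrated stress response list, 6 rose, 1 fell and 28 did not pass, and 5 passed adjusted over the list alone. The median of the list was 0.47 (limma camera adjusted p = 0.020, adjusted p = 0.822 with an estimated correlation, and fry adjusted p = 0.285), 0.74 without SKOV3ip1 collection 1, 0.83 without SKOV3TRip2 collection 1 and 0.31 without SKOV3TRip2 collection 2, and 0.29, 0.04 and 1.17 within chips 1, 2 and 3. The list's call was lost without SKOV3TRip2 collection 2 (adjusted p = 0.105) or 3 (adjusted p = 0.0811). Without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 2 or 3, the calls of PHGDH (limma adjusted p = 0.0665, 0.0815, 0.103 and 0.0878), ASNS (0.12, 0.141, 0.178 and 0.154) and SDF2L1 (0.0645, 0.075, 0.0562 and 0.0532) were lost. MANF passed without SKOV3TRip2 collection 1 (log2 -1.07, limma adjusted p = 0.0143).

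Some histone genes were higher, with H2AC18 up by log2 2.48 and H2BC21 by log2 1.91. Of 14 members, 7 rose, 0 fell and 7 did not pass, and 8 passed adjusted over the list alone, and H4C3 and MACROH2A1 both stood at -0.35. A second MACROH2A1 probe rose (log2 0.66), and H4C3 passed under quantile normalization (log2 -0.43, limma adjusted p = 0.0436). Across the list the median was 0.42, or 0.33 with members at their bound (limma camera adjusted p = 0.0158, adjusted p = 0.822 with an estimated correlation, and fry adjusted p = 0.054), and 0.76, 0.38 and 0.27 within chips 1, 2 and 3, and its call was lost without SKOV3TRip2 collection 3 (adjusted p = 0.0763).

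Cancer-testis antigens, germline genes that many tumours express, changed strongly in both directions. MAGEB2 rose at least 19.4-fold and GAGE7 at least 5.49-fold (log2 4.87 and 2.96), whereas SPANXC and SPANXD fell. Of 31 members on the array 13 were tested, of which 10 rose, 2 fell and 1 did not pass, and 12 passed adjusted over the list alone. On every array of the dimmer line, 10 of the 13 were not above background. They passed the filter only through the brighter line, which fixed their direction. The counts and list tests that follow from them are therefore no independent support for a shift. The list's median was 1.45, or 1.25 with 10 members at their bound (limma camera adjusted p = 0.00028, adjusted p = 0.781 with an estimated correlation, and fry adjusted p = 0.00624), and 1.34, 1.31 and 1.38 within chips 1, 2 and 3.

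**Figure D4:**
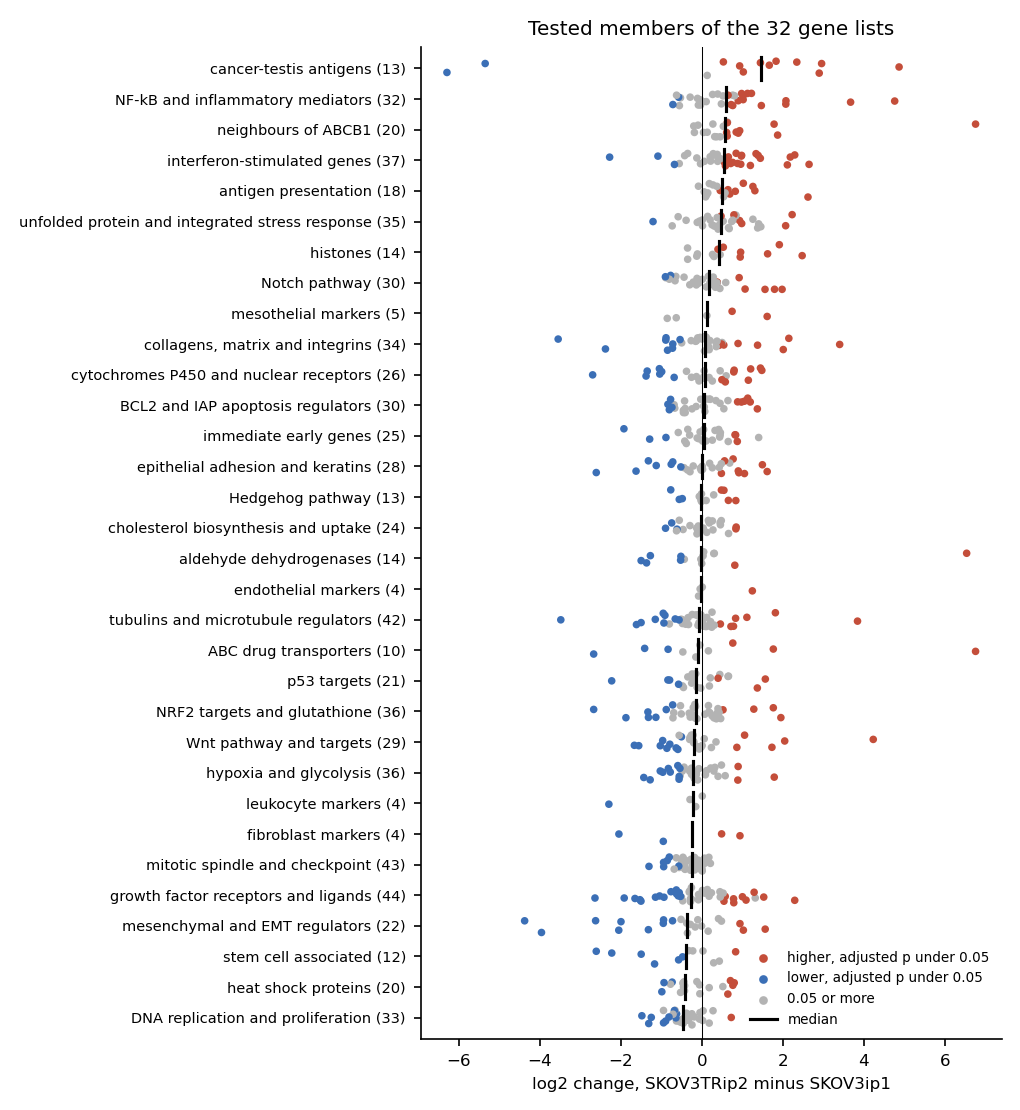
Log2 change, SKOV3TRip2 minus SKOV3ip1, of each tested member of the 32 gene lists, with the number tested in parentheses and the list median as a black bar. Red and blue points passed a limma adjusted p of 0.05, and the medians run from -0.46 for DNA replication to 1.45 for cancer-testis antigens.

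Several metabolic and stress lists held changed genes without a shift of the list. Among NRF2 targets, GSTA4 (log2 1.95) and ABCC2 rose, and GPX1 (log2 -1.87), a glutathione peroxidase, and ABCC3 fell, with 4 up, 7 down and 25 not passing of 36, and 14 passing adjusted over the list alone (limma camera adjusted p = 0.661). Among cytochromes P450 and nuclear receptors, CYP27B1 (log2 1.48) and CYP26B1 (log2 1.45) rose, and CYP24A1 (log2 -2.69), the vitamin D hydroxylase, and CYP4F11 (log2 -1.38) fell, with 8 up, 7 down and 11 not passing of 26, and 16 passing adjusted over the list alone (limma camera adjusted p = 0.813). Their median of 0.07 and mean of -0.02 differed in sign. Of 36 hypoxia and glycolysis genes, 3 rose, 10 fell and 23 did not pass, with 17 passing adjusted over the list alone (limma camera adjusted p = 0.191). PFKM (log2 1.79) and the glucose transporter SLC2A3 (log2 0.90, at least 1.25-fold) rose, and PKM (log2 -1.43) and NDRG1 (log2 -1.27) fell. The PKM call was lost without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 2 or 3 (limma adjusted p = 0.0619, 0.0736, 0.0754 and 0.0617). A second PKM probe fell (log2 -1.25, limma adjusted p = 0.00463).

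Heat shock proteins gave 4 up, 3 down and 13 not passing of 20, with 7 passing adjusted over the list alone (limma camera adjusted p = 0.667). HSPA4 (log2 0.80) and HSPA9 (log2 0.77) rose, and HSPB1 (log2 -0.99) and HSPH1 (log2 -0.93) fell. A second HSPA4 probe did not pass (log2 0.53). The calls of HSPA4 (limma adjusted p = 0.0849, 0.109, 0.0857 and 0.0764) and HSPH1 (limma adjusted p = 0.076, 0.0556, 0.0735 and 0.0661) were lost without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 2 or 3, and that of HSPA9 without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 3 (limma adjusted p = 0.0617, 0.0969 and 0.0562). Of 24 cholesterol genes, 2 rose, 3 fell and 19 did not pass, with 2 passing adjusted over the list alone (limma camera adjusted p = 0.930), and their median of -0.01 and mean of 0.00451 differed in sign. MSMO1 (log2 0.85) and STARD4 (log2 0.84) rose, and SC5D (log2 -0.90) and NSDHL (log2 -0.74) fell. A second SC5D probe stood at -0.07, and a second MSMO1 probe rose (log2 1.10, limma adjusted p = 0.0457). The calls of MSMO1 (limma adjusted p = 0.145, 0.119, 0.0868 and 0.137) and STARD4 (limma adjusted p = 0.142, 0.165, 0.112 and 0.181) were lost without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 1 or 2, and that of NSDHL without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 2 or 3 (limma adjusted p = 0.053, 0.0675, 0.0701 and 0.0572). Within chip 1 MSMO1 and STARD4 did not rise, at differences of -0.08 and -0.30.

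Among p53 targets, the oxidoreductase TP53I3 (log2 1.57) and TNFRSF10B rose, and GADD45B (log2 -2.22) and BAX fell. A second TP53I3 probe stood at 0.07. Of 21 members, 3 rose, 4 fell and 14 did not pass, with 7 passing adjusted over the list alone (limma camera adjusted p = 0.697). Among immediate early genes, CCN2 rose (log2 0.88), the phosphatase DUSP4 (log2 -1.92, at least 3.25-fold) and FOSL1 (log2 -1.29) fell, and ATF3 stood at 1.40. Of 25 members, 3 rose, 3 fell and 19 did not pass, with 6 passing adjusted over the list alone (limma camera adjusted p = 0.898), and camera pointed up and fry down. The CCN2 call was lost without SKOV3ip1 collection 2 (limma adjusted p = 0.0587), and ATF3 passed without SKOV3TRip2 collection 1 (limma adjusted p = 0.00105) and with the chip as a block (limma adjusted p = 0.0249). The FOSL1 call was lost without SKOV3ip1 collection 2 or 3 or SKOV3TRip2 collection 1 or 2 (limma adjusted p = 0.0867, 0.0937, 0.0813 and 0.0817), and within chip 1 FOSL1 did not fall, at a difference of 0.09.

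Few markers of other cell types passed the background filter: 4 of 22 leukocyte, 4 of 14 endothelial and 4 of 15 fibroblast markers on the array were tested. Of the 4 leukocyte markers, 0 rose, 1 fell and 3 did not pass, with 1 passing adjusted over the list alone. CD68, a lysosomal protein, fell by log2 -2.29, and CD79B, ITGAX and CORO1A stood at 0.01, -0.15 and -0.29. Of 4 endothelial markers, VWF rose (log2 1.25, at least 1.60-fold), and EGFL7, ERG and KDR stood at 0.01, -0.04 and -0.08, with 1 passing adjusted over the list alone. Of 4 fibroblast markers, PDGFRB (log2 0.94, at least 1.05-fold) and COL1A1 (log2 0.49, at least 1.08-fold) rose and ACTA2 (log2 -0.95) and MFAP5 (log2 -2.05) fell, and 4 passed adjusted over the list alone. The COL1A1 call was lost without SKOV3ip1 collection 1 or 2 or SKOV3TRip2 collection 1 or 2 (limma adjusted p = 0.0514, 0.0983, 0.0714 and 0.0603). These 3 lists had too few members for the list test. Of 5 mesothelial markers, KRT5 and WT1 (log2 0.75, at least 1.53-fold) rose, 0 fell and 3 did not pass, with 4 passing adjusted over the list alone (limma camera adjusted p = 0.642). MSLN and LRRN4 stood at -0.63 and -0.85. MSLN passed without SKOV3ip1 collection 2 (limma adjusted p = 0.0381), and LRRN4 without SKOV3ip1 collection 1 or SKOV3TRip2 collection 1 (limma adjusted p = 0.0274 and 0.0169). With the chip as a block both passed, at limma adjusted p = 0.0471 and 0.0419.

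Over the 29 tested lists, camera called 10, of which 7 were higher and 3 lower in SKOV3TRip2, and 0 were called with an estimated correlation, where 0 had an unadjusted p under 0.05. By fry, which asks whether the genes of a list move on balance in 1 direction, 7 lists passed, of which 4 were among the 10. Outside the 10, fry passed ABC drug transporters (upward, fry adjusted p = 0.0185) and aldehyde dehydrogenases (upward, fry adjusted p = 0.00976). It also passed genes associated with stem cells (downward, fry adjusted p = 0.00865). The transporters hold ABCB1 (log2 6.75) and the dehydrogenases ALDH1A1 (log2 6.53), against list medians of -0.10 and -0.01. Fry was not repeated without these genes, nor for the neighbours of ABCB1 without ABCB1. With the chip as a block 11 were called, the 10 among them. Without SKOV3TRip2 collection 3, 6 were called.

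**Figure D5:**
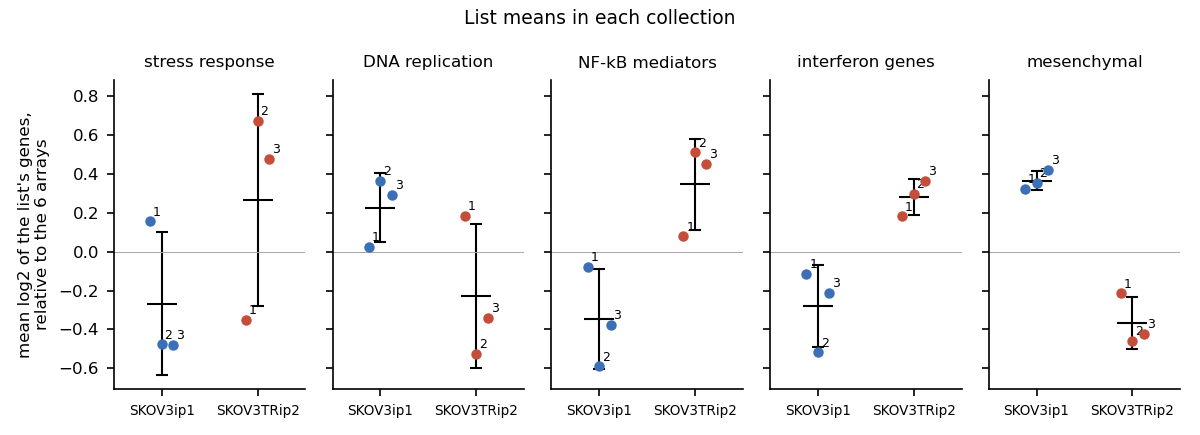
Mean log2 intensity of the tested genes of 5 lists on each array, relative to the mean of the 6 arrays, with the collection number beside each point and the mean and SD of 3 collections as bars. Stress response means run from -0.48 to 0.16 in SKOV3ip1 and from -0.35 to 0.68 in SKOV3TRip2, while the mesenchymal means of the lines do not overlap.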

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

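Averaging SKOV3ip1 collections 2 and 3 as 1 sample, removing a trend with gene length and leaving ABCB1 out of its neighbours were chosen after seeing the data. Quantile normalization, other floors, filters and backgrounds and eBayes without trend left every count of changed probes within 1.5 times the reported value. Median scaling changes almost nothing here, since the medians were already equal, and so says nothing about stability. Array weights raised the count to 6222 probes, 3163 higher and 3059 lower, while averaging the close SKOV3ip1 collections lowered it to 2069, 1072 higher and 997 lower. The averaging leaves fewer samples. The weighted fit leaned on SKOV3ip1 collection 3, at a weight of 7.31 against 0.35 to 1.54 for the other arrays, and the rise was not tested further. Leaving out 1 array gave 1864 to 4637 changed probes, 992 to 2351 higher and 872 to 2286 lower, 996 to 1609 at 2-fold or more, 525 to 792 higher and 471 to 817 lower, 6 to 11 lists and 3 to 4 genes of interest. The estimated correlation left 0 lists, and the cause was not tested. Deviations of same-numbered collections correlated at -0.40, -0.398 and 0.24, with no common sign. Arrays that shared a chip, a known pairing, gave -0.116, 0.411 and -0.444. A pairing thus need not show in this measure, so whether the numbers pair the arrays stays open. The replicate block gave 2705 probes, 1377 higher and 1328 lower, with 1186 at 2-fold or more, 10 lists and 3 genes of interest. Of 172 genes followed by name 144 were called, 116 kept their call in every alternative test, 28 lost it without 1 array, and 9 uncalled genes gained a call in some alternative. Within chip 1 the log2 differences of BIK (0.00141), MSMO1 (-0.0809), STARD4 (-0.301) and FOSL1 (0.089) were reversed against the fit, and the cause was not tested. Over 11870 named probes, 3389 were called before and 3355 after removal of the length trend, 3041 of them in both, and at 2-fold or more 1117 before and 1096 after, 975 in both. Signal over background limits the dim genes, for which a fold is a lower bound.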

Other observations

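Tests of gene order, of the spread of stress genes, of the cancer-testis families and of other splits were chosen after the result was seen. Within the gene order test, the predictions for gene length and name stems were written before their outcomes were seen. The TGF-beta list was written before its values were seen. Neighbouring genes moved together beyond ABCB1. A run of 20 tested genes from FAM222B to ADAP2 had a median log2 change of 0.95, with 14 called higher and 0 lower. The run from SAMD9L to ASNS had a median of 0.92, with 9 called higher and 2 lower, that from DAGLB to BZW2 0.85, with 8 and 0, and that from FARSB to PID1 0.71, with 10 and 1. Lower runs went from ANO10 to LZTFL1 (median -0.83, 9 called lower), from METTL26 to CHTF18 (median -0.82, 8 called lower) and from TUFT1 to ILF2 (median -0.64, 6 called lower), each with 0 called higher. The 27 genes from HARS1 to HDAC3, which take in the clustered protocadherins, had a median of 0.79 with 17 called higher and 1 lower. Changes were also related to gene length: across named probes, which are not independent, the Spearman correlation of the line difference with genomic length was 0.195. Differences between collections of the same line gave values from -0.226 to 0.333.

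Over 15 neighbouring genes, 37 windows had a median beyond the bounds of 0.83 and -0.81 set by shuffled gene orders, against at most 4 in 200 further shuffles. Chance order of genes is thereby excluded, and so is the gene length trend as the whole cause, since 35 windows remained after its removal. With 1 gene per name stem and chromosome 15 windows remained, fewer than the number fixed beforehand to exclude shared probes among related neighbours, so that part stays open. A copy number difference may raise such runs: in the run that holds ABCB1, from CCDC146 to STEAP1, 85.7% of 21 genes had a change above 0 and 14 were called higher. The run was picked by its medians, so a majority above 0 follows from the choice and is no evidence for copy number. No DNA was measured, so copy number and shared regulation cannot be told apart.

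Stress response genes differed between collections of the same line. The SD of the list mean within lines was 0.464, against a 95th percentile of 0.0801 in 10000 random lists matched on level (permutation p = 1e-04, the smallest these can give). The list was chosen for its spread, and 21 of the 28 other lists also lay beyond that percentile, so the ordinary spread of genes regulated together stays open. SKOV3ip1 and SKOV3TRip2 deviated by 0.42 and 0.21 on chip 1, by -0.21 and -0.62 on chip 2 and by -0.21 and 0.41 on chip 3. The signs were opposite on 1 of the 3 chips, so the chip stays open as well. Culture state at collection, such as medium age, could differ, and it was not tested. No biological explanation was tested, since the design names none within a line.

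Cancer-testis families moved in opposite directions. All 6 tested GAGE, 3 VCX, 5 CT45 and 6 MAGEA probes rose, and all 4 tested SPANX probes fell. Of these, 6, 3, 4, 6 and 4 were not above background on any array of the dimmer line. Such probes passed the background filter only through the brighter line, which fixed their direction. Probes dim in both lines were not tested. With probes at their bound, the median rise was at least 54.1-, 15.7-, 18.3- and 2.80-fold and the median SPANX fall at least 37.4-fold. The rise did not take in all germline genes of the X chromosome: the highest SPANX probe, at its bound, stood at log2 -3.40. The SPANX falls had been seen before this test was chosen, so it restates them and excludes no cause. Cross-hybridization among near-identical copies cannot be told apart from a change of each member: 0 of the 5 families held probes called in both directions. The line difference itself remains the open biological explanation and was not tested further.

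Because PMEPA1, TGFBI, COL5A1 and SNAI2, genes that TGF-beta can induce, were among the decreases, lower TGF-beta signalling in SKOV3TRip2 was tested as a hypothesis. In a list of 37 other TGF-beta responsive genes, 32 were tested. Of these 4 rose, 6 fell and 22 did not pass, and the median was 0.0041. It did not stand apart from 10000 random lists matched on level (two-sided permutation p = 0.868), so the test gave no evidence for the hypothesis and does not exclude it. The median took all members in a single direction, so any that TGF-beta moves in opposite ways could cancel in it.

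With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3694 probes and 1204 at 2-fold or more, with 1 split as large in each case, the real one, and the highest other split gave 1 and 1. Every other split mixes the lines, which puts the line difference into the spread within its groups. A low probe count there was fixed in advance and does not measure chance. For lists the real split gave 10 and the highest other 12, so 2 of the 10 splits called as many. That other split set SKOV3ip1 collections 1 and 2 and SKOV3TRip2 collection 1 against the rest. It keeps part of the line difference, and how much of its count came from the lines and how much from the collections was not tested.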
